A study of Drosophila melanogaster with 50 samples.

How the data were processed

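RNA was measured in 50 libraries of adult Drosophila melanogaster kept on a normal diet at 25 °C. The flies came from 2 strains, w1118 and OregonR, and both sexes. They were sampled at day 5, day 30 and, for w1118, day 45. The material was whole bodies, dissected fat body (the fly's liver-like and fat-storing organ, which also secretes immune peptides) or dissected gut. Per the labels' protocols, total RNA was extracted with Trizol and standard Illumina libraries were made. The aligner, counting tool, genome build and annotation are not given in the sources used here. The strandedness of the libraries is not given either, so reads of overlapping or antisense genes cannot be separated.

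The deposited table gives 13697 genes by symbol and FlyBase identifier, with 1 column per library and no column of another sample. It is named as TPM, but its values are expected counts: 91.46% of the values above 0 lie within 0.01 of a whole number, and the columns sum to between 2.676 and 14.41 M. The deposited expected counts were therefore rounded to whole numbers and tested as counts. The design fixed beforehand had foreseen limma on log2(TPM + 1), the test for a table in TPM. The unit found calls for a count test, so edgeR was used with the groups, contrasts, lists and alternatives kept.

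Groups were defined by strain, sex, age and tissue, 22 in all. Whole bodies of w1118, whole bodies of OregonR, fat body and gut are called the 4 systems. Separate edgeR models were fitted for whole bodies, fat body and gut, with a coefficient for each group. Counts were scaled by TMM. Genes were tested where the mean of at least 1 group reached 1 CPM (counts per M counts of the library, after scaling), which left 12381 genes in whole body, 11037 in fat body and 11830 in gut. The quasi-likelihood F test of edgeR gave p-values, adjusted by the Benjamini-Hochberg method within each contrast, and genes with an adjusted p under 0.05 were called. Age contrasts average the changes of the 2 sexes with equal weight. A sex difference is the male change minus the female change from day 5 to day 30, and the strain difference is the OregonR change minus the w1118 change. Log2 changes are given with their standard errors (SE), and levels as mean CPM ± SD over the libraries of a group. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

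The contrasts, the gene lists, the rule for naming genes and the settings to compare were fixed before the data were examined. The rule named the 10 rising and 10 falling genes with the largest change at day 30 in each system, among called genes with the same direction in both sexes and a mean of at least 5 CPM in some group. It named 5 on each side for day 45, and 5 on each side for sex and strain differences. For each list it named up to 4 called members with the largest change, or up to 2 members where none was called, and it named all genes changed alike in the 4 systems. The rule had been written for TPM and was applied to CPM. Some named genes that repeat a group already described are left out of the text. Some list members outside this rule are named as examples and were chosen after the values were seen.

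The 22 lists cover antimicrobial effectors, Toll and Imd recognition and signalling, JAK-STAT with Turandot and thioester genes, hemocyte markers, the mitochondrial respiratory chain, glycolysis, cytosolic ribosomal proteins, heat shock proteins and chaperones, proteasome subunits, glutathione transferases and antioxidants, digestive enzymes, lipid metabolism, insulin and FOXO signalling, stem cell and cell cycle genes, enteroendocrine peptides, Malpighian tubule markers, ovary and eggshell, testis, male accessory gland and ejaculatory duct, muscle structure, neurons and photoreceptors, and the circadian clock. Fixed symbols with no match among the symbols of the table were not used here, among them RpL34, RpSA, Hsp67Bb, NHA1, dec-1, twine, Peb and Rh6. Each list was tested with fry on edgeR's z-scores of the counts, in the same design. The directional p-value of fry asks whether the members of a set move, on balance, one way, and it compares the set with no other set. The 154 tests of lists in the 7 contrasts with day 5 were adjusted as a family, and the 176 tests in the 8 other contrasts, added later, as another. A count of list members is given over all genes tested and adjusted over the list alone. Where a group had no counts, a fitted fold change depends on the prior count and is not read as a fold, so levels are given.

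Markers of other tissues were followed as shares of each library's counts. A set of 30 fat body markers was taken from the libraries themselves, as the genes of at least 100 CPM in fat body at day 5 with the highest ratio of fat body to gut at that age, leaving out members of the immune, muscle, heat shock, ovary, testis and accessory gland lists. It is not independent of these libraries. It includes the cuticle genes Acp65Aa, Cpr49Ab and Cpr49Ae, so part of it may mark other tissue in the dissected fat body. Symbols were compared with an Ensembl annotation of the BDGP6.54 assembly, in which 13639 (99.58%) of the identifiers occur. That annotation was used for exonic length alone, and no coordinates are given because the build of the deposited table is not stated.

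The labels do not say whether replicates came from separate flies, vials or dissections, so the p-values measure the spread between these samples, which may be technical. All 37 replicate pairs differed by more than sampling noise (lowest chi-square per gene, 1.91) and their log CPM values correlated across genes at 0.928 to 0.995. The lowest belongs to male day 5 gut replicates 2 and 3, which stood at 22.9 and 20.2 from replicate 1, so this pair may be repeats of the same sample. It was kept as separate libraries, and the counts without either are given in the report. Groups held 1 to 3 libraries, too few for a test of a library standing apart from its group.

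Simulated counts with the means and depths of each system, with 100 genes changed 2-fold and 100 changed 4-fold, were run through the same test. The changed genes were drawn among those with a mean of at least 5 CPM, and each library was simulated as a separate sample. The recovery therefore does not cover lower genes or repeats of the same sample. In w1118 whole body 75% of the 2-fold and 88% of the 4-fold changes were recovered among 12302 genes, with 3.55% of the calls false. The values were 67%, 80% and 2.65% over 12298 genes in OregonR whole body, 50%, 92% and 4.70% over 10701 genes in fat body, and 59%, 80% and 2.80% over 11688 genes in gut.

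The settings compared were scaling by the median of ratios, no filter on low counts, the replicate number as a block, a pseudocount of 0.1 (limma with trend on log2(CPM + 0.1)), and leaving out each library in turn. Added after the data were seen were DESeq2, limma with trend on log2(CPM + 1), each sex alone, fits without day 45, counts thinned to the smallest library of the tissue, and gut without sex-biased genes. Ages were also reassigned among the libraries within each sex, with all assignments used where there were at most 100 and 100 drawn at random (seed 1) otherwise. With 1 library per sex in fat body at day 45, no such reassignment was run there. Near-identical copies such as the Hsp70, histone, attacin and Jonah genes share reads, so their separate values are uncertain.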

Results

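The series measured the transcriptomes of ageing Drosophila to compare age-related expression, immune genes among them, across strains, sexes and tissues. It holds 50 libraries in 22 groups. Whole bodies of w1118, a white-eyed laboratory strain, were sampled at days 5, 30 and 45 in each sex, with 2 libraries per group and 3 for day 45 males. Whole bodies of OregonR, a wild-type strain, were sampled at days 5 and 30 with 2 libraries per group. Fat body and gut of w1118 had 3 libraries per sex at days 5 and 30. At day 45 fat body had 1 library per sex, and gut had 2 of females and 1 of males. Total counts per library were 11.95 to 14.41 M in w1118 whole body (13 libraries) and 4.357 to 6.512 M in OregonR whole body (8 libraries). In fat body and gut they were 2.676 to 4.609 M at days 5 and 30 (24 libraries) and 12.34 to 13.72 M at day 45 (5 libraries). Day 45 and depth therefore go together in these tissues.

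The genes that check the labels matched them. The eye pigment transporter gene w stood at 0 to 3.78 CPM in the 42 libraries of w1118, which lacks most of this gene, and at 8.09 to 19.5 CPM in the 8 of OregonR. Yp1, a yolk protein gene made by females, stood at 3390 to 61900 CPM in the 17 female whole body and fat body libraries and at 843 to 7570 CPM in the 8 of female gut. In the 25 male libraries Yp1 stood at 0.174 to 48.9 CPM. Yp2 (2700 to 32400, 507 to 3940 and 0.703 to 21.5 CPM) and Yp3 (1990 to 29300, 431 to 3720 and 2.22 to 23.5 CPM) separated the sexes in the same way.

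Between day 5 and day 30, w1118 whole bodies lost transcripts of muscle, blood cells and mitochondria (n = 2 libraries per sex and age). Of the 27 muscle structure genes, 23 fell and 0 rose (23 and 1 adjusted over the list alone), with a median log2 change of -0.72 (fry, adjusted p = 1.15e-06). TpnC4, a troponin C, fell from 49.0 ± 12.6 to 0.676 ± 0.385 CPM in females and from 176 ± 5.03 to 4.20 ± 2.85 CPM in males. Its log2 change was -5.77 (SE 0.39, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.14e-08). The flight muscle gene fln (-4.70, SE 0.29) and TpnC41C (-2.12, SE 0.13) fell as well, and Scp1, a sarcoplasmic calcium-binding protein gene outside the list, by -3.87 (SE 0.11, edgeR adjusted p = 4.75e-13). Of 18 hemocyte markers, 13 fell (14 adjusted over the list alone, median -0.93, fry, adjusted p = 1.08e-05). They included the prophenoloxidase genes PPO2 (-4.30, SE 0.20) and PPO1 (-4.08, SE 0.18) and the phagocytic receptor gene eater (-1.81, SE 0.18). Of 67 respiratory chain genes, 64 fell (67 adjusted over the list alone), by a median of -0.60 (fry, adjusted p = 0.000228). ND-MLRQ, a subunit of complex I, went from 456 ± 108 to 152 ± 1.42 CPM in males and from 163 ± 2.87 to 107 ± 14.8 CPM in females. In glycolysis 8 of 19 genes fell and 1 rose (10 and 1 adjusted over the list alone, median -0.26, fry, adjusted p = 0.0111), led by Ald1 (-1.14, SE 0.10).

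Antimicrobial effectors, the peptides that kill microbes in blood and gut, went both ways in these w1118 flies. Of 40, 2 rose and 3 fell (1 and 2 adjusted over the list alone, median -0.04, fry, adjusted p = 0.973). The diptericin gene DptA went from 0.729 ± 0.260 to 18.1 ± 1.06 CPM in females and from 74.0 ± 53.3 to 36.7 ± 6.49 CPM in males. Malpighian tubule markers rose in 5 of 15 cases (6 adjusted over the list alone, median 0.33, fry, adjusted p = 0.0166), among them the urate oxidase gene Uro (1.48, SE 0.34). Ovary and eggshell genes rose in 4 of 33 cases (3 adjusted over the list alone, median 0.50, fry, adjusted p = 0.036). The eggshell gene Cp15 went from 25.0 to 972 CPM in females and from 2.39 to 1.24 CPM in males. In females the list took 1.96% and 2.05% of the counts at day 5, then 1.81% in replicate 1 and 3.03% in replicate 2. Its female rise in share therefore rests on replicate 2. Male shares were 0.0196% and 0.0206%, then 0.0325% and 0.0291%. Among genes outside the lists, CG10814 rose by 5.58 (SE 0.63), CG5770 by 3.30 (SE 0.32) and CG9150 by 3.12 (SE 0.29), while CG15617 fell by 4.97 (SE 0.29). In all, edgeR called 1723 of 12381 genes, 1029 higher and 694 lower. Scaling by the median of ratios moved the share of higher calls from 59.7% to 46.7%. Without a single library the count dropped to 728 (female day 5 replicate 2), 803 (male day 30 replicate 1), 937 (female day 30 replicate 1) or 973 (male day 5 replicate 1).

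OregonR whole bodies also lost muscle and mitochondrial transcripts by day 30, and immune genes rose (n = 2 libraries per sex and age). Of the 27 muscle genes, 23 fell (25 adjusted over the list alone, median -0.84, fry, adjusted p = 6.9e-07). Act79B, a muscle actin, fell from 327 ± 5.04 to 37.2 ± 1.27 CPM in females and from 626 ± 35.7 to 125 ± 1.53 CPM in males, and TpnC4 fell by 2.83 on the log2 scale (SE 0.38). Scp1 fell by 4.31 (SE 0.12, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.13e-13). The respiratory chain had 37 of 67 genes lower (50 adjusted over the list alone, median -0.43, fry, adjusted p = 0.00257). In glycolysis 10 of 19 fell and 1 rose (10 and 2 adjusted over the list alone, median -0.36, fry, adjusted p = 0.0126), with Gapdh1 at -1.05 (SE 0.09). Of 32 genes of neurons and photoreceptors, 17 fell and 1 rose (20 and 2 adjusted over the list alone, median -0.52, fry, adjusted p = 0.00081). They included the photoreceptor channel gene trpl (-1.24, SE 0.11) and Gad1, which makes the transmitter GABA (-1.14, SE 0.11). Hemocyte markers fell in 5 of 18 cases (5 lower and 1 higher adjusted over the list alone, median -0.09, fry, adjusted p = 0.0152), led by PPO1 (-3.07, SE 0.22) and PPO2 (-2.66, SE 0.21).

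Among 41 Toll and Imd genes of OregonR, 7 rose (10 adjusted over the list alone, median 0.07, fry, adjusted p = 0.00472). They included the recognition genes PGRP-SB1 (1.85, SE 0.50) and PGRP-SD (1.51, SE 0.25) and the Imd inhibitor gene pirk (1.79, SE 0.29). Of 40 antimicrobial effectors, 6 rose (7 adjusted over the list alone), among them AttA (4.30, SE 1.01) and CecA1 (3.44, SE 0.74), but the list as a whole missed the threshold (median 0.78, fry, adjusted p = 0.0674). With the counts of 1 library left out it passed, at 0.96 without female day 30 replicate 2 (fry, adjusted p = 0.0426) and at 1.24 without male day 5 replicate 1 (fry, adjusted p = 0.0428). It also passed with a pseudocount of 0.1 (median 0.80, fry, adjusted p = 0.0336) and without the day 45 libraries (median 0.77, fry, adjusted p = 0.0498). The same held with the replicate number as a block, as given with the settings below. In 5 other settings of the processing the list did not pass, as in the main fit. Of the 18 assignments of ages to these libraries, 3 gave an effector median at least as large, the real one included. The midgut progenitor genes Sox21a (2.73, SE 0.64) and esg (1.59, SE 0.25) rose, though the stem cell and cell cycle list did not move together (2 higher and 3 lower of 39, and the same counts adjusted over the list alone, median -0.10, fry, adjusted p = 0.457). Digestive enzymes went both ways, with 9 of 49 higher and 11 lower (13 and 16 adjusted over the list alone, fry, adjusted p = 0.973). In all, 826 of 12381 genes were called, 327 higher and 499 lower. The count was 448 without female day 30 replicate 1 and 524 without female day 5 replicate 1.

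In fat body, 30-day flies had lower levels of muscle and blood cell transcripts than 5-day flies, and of some cuticle and heat shock transcripts (n = 3 libraries per sex and age). Of 27 muscle genes, 25 fell (26 adjusted over the list alone, median -1.33, fry, adjusted p = 0.00112). Act79B went from 837 ± 350 to 22.6 ± 7.02 CPM in males and from 181 ± 120 to 14.8 ± 4.71 CPM in females. The muscle list took 3.02% (SD 0.715) of the counts of female fat body at day 5 and 1.47% (SD 0.106) at day 30. In males it took 2.77% (SD 0.769) and 1.42% (SD 0.249). The cuticle protein genes Acp1, Acp65Aa and Cpr92F belonged to the largest falls, with male means of 805 ± 795, 252 ± 235 and 504 ± 503 CPM at day 5, and 0, 0 and 0.460 ± 0.411 CPM at day 30. The SDs show how unevenly the day 5 libraries carried them. Hemocyte markers fell in 8 of 18 cases (13 lower and 2 higher adjusted over the list alone, median -1.02, fry, adjusted p = 0.00937). They included the phagocytosis receptor gene NimC4 (-3.94, SE 0.59), Pxn (-1.68, SE 0.20) and Hml (-1.32, SE 0.23). Heat shock and chaperone genes fell in 10 of 25 cases (16 adjusted over the list alone, median -2.65, or -2.58 with members without counts at their bound of 3 counts, fry, adjusted p = 0.0436). The near-identical Hsp70 copies together took 0.295% (SD 0.259) of the counts in females at day 5 and 0.00274% (SD 0.00302) at day 30. In males they took 0.279% (SD 0.404) and 0.0395% (SD 0.0153), and the male value of day 5 rests on replicate 1 at 0.745%. Replicates 2 and 3 held 0.0476% and 0.044%, within the 0.0223% to 0.052% of day 30. Genes of neurons and photoreceptors fell in 6 of 22 cases (11 adjusted over the list alone, median -0.57, fry, adjusted p = 0.0233). Respiratory chain genes fell in 8 of 67 (16 adjusted over the list alone, median -0.29, fry, adjusted p = 0.0436). Malpighian tubule markers went both ways, with 4 of 15 called lower (5 adjusted over the list alone, median 0.31, fry, adjusted p = 0.331). Their share went from 0.0733% (SD 0.00758) to 0.0303% (SD 0.0128) in females and from 0.0314% (SD 0.00568) to 0.0403% (SD 0.0101) in males. Male accessory gland genes went from 0.526% (SD 0.226) to 0.139% (SD 0.120) of male counts, with 0 of 28 called by edgeR (0 adjusted over the list alone, median 1.37, fry, adjusted p = 0.419).

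Fewer genes rose in fat body than fell. Insulin and FOXO signalling genes rose in 3 of 19 cases (5 adjusted over the list alone, median 0.27, fry, adjusted p = 0.0152). The insulin-like peptide gene Ilp6 went from 36.8 ± 10.7 to 91.0 ± 13.6 CPM in females and from 51.1 ± 6.19 to 87.2 ± 19.7 CPM in males (log2 1.04, SE 0.16, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0053), and Thor, a FOXO target, rose by 0.80 (SE 0.18), by 1.45 in females and 0.14 in males. The sterol transport genes Npc2e (4.76, SE 0.73) and Npc1b (3.80, SE 0.49), Arc1 (2.21, SE 0.43, or 0.81 in females and 3.61 in males) and the fatty acid synthase gene FASN3 (1.06, SE 0.20) rose too. The maltase gene Mal-A7 was called higher (3.22, SE 0.72), from 0.968 ± 0.548 to 57.3 ± 51.5 CPM in females and from 50.7 ± 11.8 to 80.5 ± 84.4 CPM in males. It belongs to the digestive enzymes, whose share of fat body counts at days 5 and 30 varied from 0.0538% to 1.18% between libraries. Antimicrobial effectors did not move together (0 of 38 higher and 2 lower, 1 and 2 adjusted over the list alone, median 0.16, fry, adjusted p = 0.667). The members that fell were Def (-3.46, SE 0.84) and Drs (-3.44, SE 0.65), and Drs stood at 1343 ± 325 and 79.5 ± 71.6 CPM in females. Called genes numbered 699 of 11037, 153 higher and 546 lower. The count fell to 322 without male day 30 replicate 3, 350 without male day 30 replicate 2, 367 without male day 5 replicate 2, 418 without female day 5 replicate 3, 432 without female day 30 replicate 1 and 453 without male day 30 replicate 1.

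In gut, antimicrobial effectors, Toll and Imd genes and JAK-STAT genes rose by day 30, while digestive enzyme genes fell (n = 3 libraries per sex and age). Of 36 antimicrobial effectors, 22 rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 change of 1.77 (1.78 in females and 1.77 in males, fry, adjusted p = 0.000178). DptA went from 5.81 ± 1.32 to 223 ± 56.4 CPM in males and from 5.87 ± 3.0 to 54.4 ± 70.5 CPM in females (log2 4.24, SE 0.64, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00247). AttA rose by 3.72 (SE 0.33) and Drsl2 by 4.22 (SE 1.02). Of 41 Toll and Imd genes, 14 rose and 2 fell (18 and 2 adjusted over the list alone, median 0.36, fry, adjusted p = 0.000943). They included PGRP-SB1 (3.13, SE 0.32) and the Toll-activating protease gene psh (2.28, SE 0.53, or 3.86 in females and 0.71 in males). Of 17 JAK-STAT, Turandot and thioester genes, 6 rose and 1 fell (11 and 1 adjusted over the list alone, median 1.12, fry, adjusted p = 0.00132), with TotM at 4.05 (SE 0.93) and Tep2 at 1.99 (SE 0.23). Lipid genes rose in 14 of 33 cases (16 adjusted over the list alone, median 0.36, fry, adjusted p = 0.00152), including FASN3 (3.97, SE 0.61), FASN2 (2.31, SE 0.50) and the lipoprotein gene apolpp (1.83, SE 0.34). FASN3 and FASN2 belong to the 30 fat body markers, whose share of gut counts rose as well. Insulin and FOXO genes rose in 5 of 19 cases (7 adjusted over the list alone, median 0.51, fry, adjusted p = 0.00132), led by the insulin-binding ImpL2 (1.86, SE 0.24) and the receptor gene InR (1.01, SE 0.16).

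Digestive enzyme genes of the gut fell in 20 of 51 cases and rose in 1 (25 and 3 adjusted over the list alone, median -1.03, fry, adjusted p = 0.0129). The serine protease Jon99Fi went from 1255 ± 511 to 52.0 ± 33.9 CPM in females and from 220 ± 55.7 to 46.1 ± 13.2 CPM in males. The trypsin gene zetaTry fell by 4.67 in females and 0.75 in males, a called sex difference (3.93, SE 0.88, Benjamini-Hochberg adjusted p = 0.0204). Heat shock and chaperone genes fell in 13 of 25 cases (19 adjusted over the list alone), but their list test missed the threshold (median -1.84, fry, adjusted p = 0.0631). In males the day 5 share of the Hsp70 copies rests on replicate 1 at 0.614% of counts, while replicates 2 and 3 held 0.0224% and 0.0236%, within the 0.0152% to 0.0448% of day 30. Stem cell and cell cycle genes rose in 7 of 39 cases (16 adjusted over the list alone, median 1.01, fry, adjusted p = 0.0915), among them Sox21a (2.53, SE 0.64) and RnrL (1.62, SE 0.37). Transcripts of other organs moved at the same time. The 30 fat body markers took 0.0149% (SD 0.00377) of the counts of female gut at day 5 and 0.248% (SD 0.00585) at day 30, and 0.184% (SD 0.143) and 0.621% (SD 0.151) in males. The yolk protein genes Yp1 to Yp3, which fat body makes too, went from 0.178% (SD 0.0424) to 1.10% (SD 0.342) of female gut counts. The rest of the ovary and eggshell list held 0.0367%, 0.00203% and 0.00538% in the day 5 libraries and 0.00457%, 0.157% and 0.199% in those of day 30. Testis genes went from 1.30% (SD 0.0547) to 0.430% (SD 0.124) of male gut counts, and male accessory gland genes from 3.19% (SD 0.783) to 1.67% (SD 0.426). As lists, testis (0 of 32 higher and 1 lower, also 0 and 1 adjusted over the list alone, fry, adjusted p = 0.419) and accessory gland (0 of 35 called, 0 adjusted over the list alone, fry, adjusted p = 0.973) missed the threshold in gut. In all, 1514 of 11830 genes were called, 1057 higher and 457 lower. Scaling by the median of ratios moved the median of all genes from 0.08 to -0.07 and the share of higher calls from 69.8% to 41.8%, with the medians of the lists named here keeping their sign. The count was 818 without male day 30 replicate 2, 819 without male day 5 replicate 3, 848 without female day 30 replicate 2, 866 without male day 5 replicate 2 and 907 without male day 30 replicate 1.

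**Figure D1:**
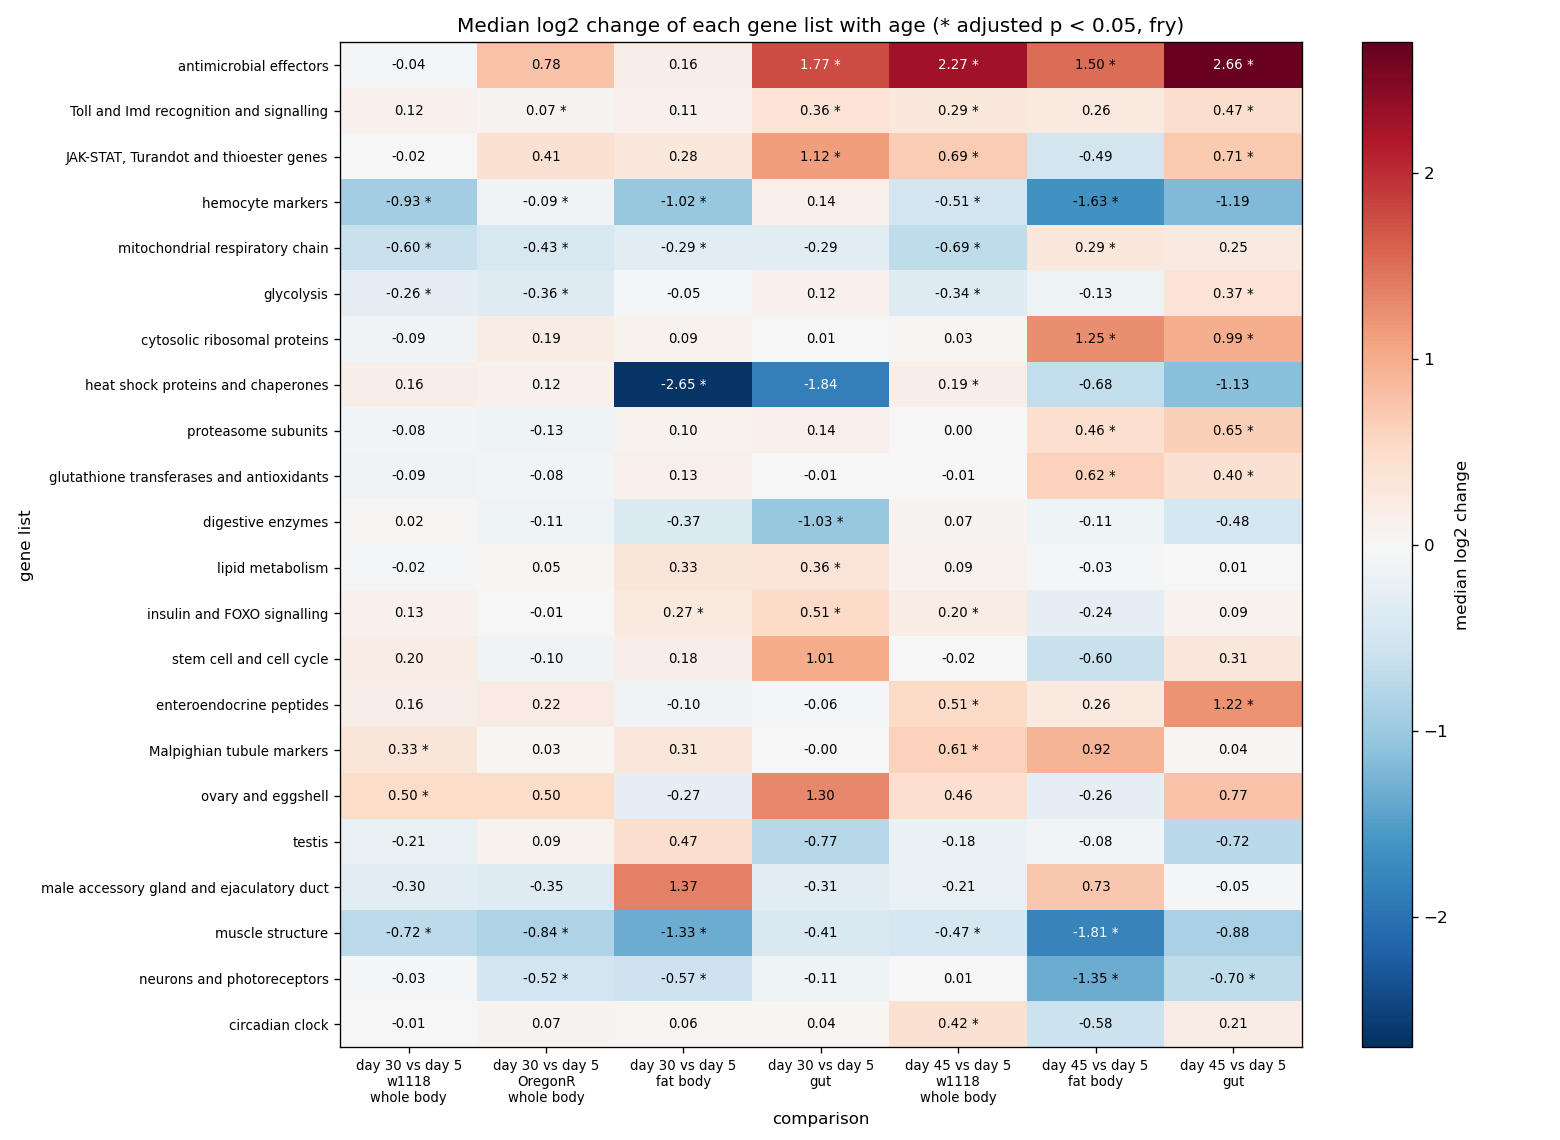
Median log2 change of the tested members of each gene list (vertical axis) in each comparison with day 5 (horizontal axis), with the value printed in each cell and an asterisk where the fry test gave an adjusted p under 0.05. Antimicrobial effectors had medians of -0.04, 0.78, 0.16 and 1.77 at day 30 in w1118 whole body, OregonR whole body, fat body and gut, and muscle structure was negative in all 7 columns.

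A small set of genes changed alike at day 30 in all 4 systems. Act79B (FBgn0000045), a muscle actin, fell by a mean of -2.99 over the 4 systems, and the cuticle protein gene Cpr49Ae (FBgn0033728) by -2.99. Act88F (FBgn0000047), another muscle actin, fell in all 4. In gut it lay near the floor, from 4.05 ± 5.33 to 0 CPM in females and from 0.95 ± 0.721 to 0.481 ± 0.417 CPM in males. Its gut call was close to the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0497). SdhD (FBgn0039112, mean -0.59) and ATPsynB (FBgn0019644, mean -0.55), subunits of respiratory complexes II and V, fell as well, as did CG42700 (FBgn0261611, mean -0.96) and CG2082 (FBgn0027608, mean -0.66). The larval storage protein gene Lsp1gamma (FBgn0002564) fell in all 4, from 61.5 ± 98.5 to 0.108 ± 0.187 CPM in female gut, for example. CG15784 (FBgn0029766, mean 0.86) rose. Among 10758 genes tested in all 4 systems, 8 fell and 1 rose, against 0.0477 and 0.0404 for independent lists. Fat body, gut and w1118 whole bodies come from the same strain, but no library is shared between these comparisons. The total of 9 became 14 without male day 5 gut replicate 1. It became 3 without male day 5 gut replicate 2 or male day 30 gut replicate 1, and 4 without female day 5 gut replicate 3, female day 30 gut replicate 2, male day 5 gut replicate 3, male day 30 gut replicate 2 or male day 30 fat body replicate 2. It became 5 without female day 30 gut replicate 3, male day 5 fat body replicate 2, or male day 30 fat body replicate 1 or 3.

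Pairs of systems shared more calls. Whole bodies of w1118 and OregonR had 215 lower genes in common (25.1 for independent lists) and 82 higher (29.4), with 10 lower in w1118 and higher in OregonR (17.95) and 8 the other way (41.1). Fat body shared 165 lower genes with w1118 whole body (30.7) and 151 with OregonR whole body (21.8), but 17 higher genes with w1118 whole body (14.3). Gut shared 185 higher genes with w1118 whole body (98.4), 83 with OregonR whole body (30.4) and 52 with fat body (14.8), and 29 lower genes with fat body (20.5). Of the genes lower in fat body 64 were higher in gut (52.1 for independent lists), and of those lower in w1118 whole body 85 were higher in gut (60.0).

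By day 45, immune genes stood above their day 5 level in w1118 whole bodies (n = 2 libraries per group, 3 for day 45 males). Muscle and respiratory chain transcripts stayed low. Of 40 antimicrobial effectors, 22 rose and 1 fell against day 5 (27 and 1 adjusted over the list alone, median 2.27, fry, adjusted p = 0.00737). In females they took 0.092% and 0.101% of the counts at day 5 and 0.432% and 0.202% at day 45. In males they took 0.552% and 0.432%, then 0.637%, 1.33% and 0.52%, so the male rise in share rests mainly on replicate 2. DptA stood at 327 ± 262 CPM in day 45 females and 545 ± 198 CPM in day 45 males, 5.83 (SE 0.46) on the log2 scale above day 5 over both sexes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.73e-07). AttA rose by 4.96 (SE 0.89) and Mtk by 4.83 (SE 0.99). Toll and Imd genes rose in 17 of 41 cases (20 adjusted over the list alone, median 0.29, fry, adjusted p = 1.3e-05), including PGRP-SB1 (2.76, SE 0.44). JAK-STAT, Turandot and thioester genes rose in 9 of 18 (10 higher and 1 lower adjusted over the list alone, median 0.69, fry, adjusted p = 0.000259), including the ligand gene upd3 (2.65, SE 0.55). Respiratory chain genes fell in 66 of 67 cases (67 adjusted over the list alone, median -0.69, fry, adjusted p = 4.19e-05). Muscle genes fell in 18 of 27 and rose in 2 (20 and 2 adjusted over the list alone, median -0.47, fry, adjusted p = 1.28e-05). Hemocyte markers fell in 9 of 18 (10 lower and 1 higher adjusted over the list alone, median -0.51, fry, adjusted p = 0.000262). Glycolysis genes fell in 10 of 19 with 1 higher (11 and 1 adjusted over the list alone, median -0.34, fry, adjusted p = 0.00907).

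Malpighian tubule, enteroendocrine and clock genes rose as well by day 45 in w1118 whole bodies. Tubule markers were higher in 11 of 15 cases (13 adjusted over the list alone, median 0.61, fry, adjusted p = 0.000104), with Uro going from 5.18 ± 0.773 to 51.6 ± 10.5 CPM in females. Enteroendocrine peptide genes were higher in 7 of 12 (8 adjusted over the list alone, median 0.51, fry, adjusted p = 0.000372), among them AstA (1.0, SE 0.18, or 1.75 in females and 0.25 in males). Clock genes were higher in 5 of 10 (5 adjusted over the list alone, median 0.42, fry, adjusted p = 0.00132), with per at 1.08 (SE 0.15). Insulin and FOXO genes were higher in 7 of 22 and lower in 1 (8 and 1 adjusted over the list alone, median 0.20, fry, adjusted p = 0.00499). Heat shock genes were higher in 5 of 25 and lower in 4 (8 and 4 adjusted over the list alone, median 0.19, fry, adjusted p = 0.0115). In all, 2821 of 12381 genes were called against day 5, 2067 higher and 754 lower, and the share of higher calls went from 73.3% to 56.2% when counts were scaled by the median of ratios.

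Between day 30 and day 45 immune genes of w1118 whole bodies rose, effectors among them. The share of the 30 fat body markers rose too, from 0.283% and 0.374% to 0.483% and 0.706% in females. In males it went from 0.973% and 1.48% to 2.11%, 2.71% and 2.69%. At day 5 it had been 0.604% and 0.666% in females and 2.5% and 2.17% in males. Of 40 antimicrobial effectors, 27 rose (34 adjusted over the list alone, median 1.87, fry, adjusted p = 0.00858), led among genes with counts in every group by DptB (4.46, SE 0.76), Mtk (4.27, SE 0.88), Dro (4.04, SE 0.87) and DptA (4.04, SE 0.39). Toll and Imd genes rose in 14 of 41 cases and fell in 1 (19 and 1 adjusted over the list alone, median 0.18, fry, adjusted p = 0.000451). JAK-STAT, Turandot and thioester genes rose in 4 of 18 (7 adjusted over the list alone, median 0.43, fry, adjusted p = 0.0054). Hemocyte markers rose in 7 of 18 (13 adjusted over the list alone, median 0.45, fry, adjusted p = 0.00433), with eater at 1.15 (SE 0.18). Muscle genes rose in 10 of 27 (11 adjusted over the list alone, median 0.23, fry, adjusted p = 0.00734). The clock genes per (1.42, SE 0.15) and vri (1.11, SE 0.11) rose, within a list that had 3 of 10 higher (4 adjusted over the list alone, median 0.28, fry, adjusted p = 0.00433). Malpighian tubule markers rose in 5 of 15 (7 adjusted over the list alone, median 0.36, fry, adjusted p = 0.00734) and enteroendocrine peptide genes in 1 of 12 (1 adjusted over the list alone, median 0.34, fry, adjusted p = 0.00734). The digestive protease genes Jon99Fi (-2.33, SE 0.35), Jon66Ci (-2.23, SE 0.43) and Jon99Fii (-2.0, SE 0.23) fell and the lipase gene Lip3 rose (2.10, SE 0.29), within a list that went both ways (6 of 49 higher and 7 lower, 8 and 11 adjusted over the list alone, median -0.12, fry, adjusted p = 0.83). Calls numbered 1113 of 12381, 947 higher and 166 lower by edgeR. The count was 481 without female day 30 replicate 1, 561 without male day 30 replicate 1, 683 without female day 45 replicate 2 and 700 without male day 30 replicate 2.

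In fat body at day 45, ribosomal protein genes stood above day 5, and so did antimicrobial genes averaged over the sexes. A single library per sex stood behind the later age. Of 81 ribosomal protein genes, 78 rose (79 adjusted over the list alone, median 1.25, fry, adjusted p = 0.000446). RpL36A went from 112 ± 25.6 to 1451 CPM in females and from 115 ± 23.8 to 1347 CPM in males (log2 3.63, SE 0.18). By share of counts, antimicrobial effectors stood above day 5 in the female library alone. They took 1.33% there, against 0.346% to 0.752% in females at day 5. The male library held 0.657%, within the 0.276% to 1.4% of males at day 5. Antimicrobial effectors rose in 13 of 38 cases (15 adjusted over the list alone, median 1.5, fry, adjusted p = 0.00394), led by Listericin (5.69, SE 0.51, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.22e-05). Proteasome genes rose in 15 of 32 (16 adjusted over the list alone, median 0.46, fry, adjusted p = 0.00758). Glutathione and antioxidant genes rose in 20 of 46 (22 adjusted over the list alone, median 0.62, fry, adjusted p = 0.00171), and respiratory chain genes in 21 of 67 with 2 lower (21 and 3 adjusted over the list alone, median 0.29, fry, adjusted p = 0.0434). Muscle genes fell in 20 of 27 cases (24 lower and 1 higher adjusted over the list alone, median -1.81, fry, adjusted p = 0.00257). Hemocyte markers fell in 11 of 18 with 2 higher (13 and 2 adjusted over the list alone, median -1.63, fry, adjusted p = 0.0105). Genes of neurons and photoreceptors fell in 12 of 22 (12 lower and 1 higher adjusted over the list alone, median -1.35, fry, adjusted p = 0.00291). The lipoprotein gene apolpp fell by 2.68 (SE 0.38). Against day 30 the ribosomal protein genes were again higher, in 77 of 81 cases (79 adjusted over the list alone, median 1.15, fry, adjusted p = 0.00364). So were respiratory chain genes in 46 of 67 (50 adjusted over the list alone, median 0.63, fry, adjusted p = 0.00734). Antimicrobial effectors rose in 11 of 38 (14 adjusted over the list alone, median 1.26, fry, adjusted p = 0.0155). Glutathione and antioxidant genes rose in 10 of 46 with 1 lower (12 and 1 adjusted over the list alone, median 0.53, fry, adjusted p = 0.0121) and proteasome genes in 12 of 32 (15 adjusted over the list alone, median 0.39, fry, adjusted p = 0.0414). Insulin and FOXO genes fell in 7 of 19 with 1 higher (8 and 1 adjusted over the list alone, median -0.39, fry, adjusted p = 0.00872). Replication-dependent histone genes took 0.0961% (SD 0.136) of female fat body counts at day 30 and 0.00263% at day 45, and 0.0239% (SD 0.00113) and 0.00273% in males. The female mean of day 30 rests on replicate 3 at 0.253%, with replicates 1 and 2 at 0.0155% and 0.0196%. EdgeR called 3441 of 11037 genes against day 5, 1552 higher and 1889 lower, and 2473 against day 30, 1094 higher and 1379 lower. Over all genes the change against day 30 also ran along exonic length. The median was 0.56 in the lowest quartile of length and -0.817 in the highest, against -0.0532 and 0.00876 in w1118 whole bodies. Lists other than the ribosomal protein and histone genes were not corrected for this trend. Day 45 libraries were sequenced about as deeply as w1118 whole bodies, and the earlier fat body libraries were not. Age and any library batch therefore cannot be told apart here.

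In gut at day 45, antimicrobial effectors and ribosomal protein genes were higher than at day 5 (n = 2 female and 1 male library at day 45). The 2 female libraries stood far apart, at a chi-square per gene of 173, against at most 41.7 between w1118 whole bodies of like depth. Effectors took 0.207% and 0.46% of their counts, and the yolk protein genes 0.231% and 1.43%. Of 36 effectors, 25 rose (27 adjusted over the list alone, median 2.66, or 2.73 with members without counts at their bound, fry, adjusted p = 3.19e-05). DptA reached 656 ± 597 CPM in females and 899 CPM in the male library, from 5.87 ± 3.0 and 5.81 ± 1.32 CPM (log2 7.05, SE 0.73). The defensin gene Def rose by 6.80 (SE 0.40, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.22e-07) and Drs by 6.50 (SE 0.59). Toll and Imd genes rose in 14 of 41 cases and fell in 2 (16 and 2 adjusted over the list alone, median 0.47, fry, adjusted p = 0.00499). JAK-STAT, Turandot and thioester genes rose in 6 of 17 with 1 lower (6 and 1 adjusted over the list alone, median 0.71, fry, adjusted p = 0.00499). Ribosomal protein genes rose in 80 of 81 (81 adjusted over the list alone, median 0.99, fry, adjusted p = 0.000507). Proteasome genes rose in 24 of 32 (28 adjusted over the list alone, median 0.65, fry, adjusted p = 0.00109) and glutathione and antioxidant genes in 16 of 47 (17 adjusted over the list alone, median 0.40, fry, adjusted p = 0.0234). Enteroendocrine peptide genes rose in 8 of 12 (9 higher and 1 lower adjusted over the list alone, median 1.22, fry, adjusted p = 0.000259), including CCHa1 (2.50, SE 0.33) and Tk (2.45, SE 0.24). Glycolysis genes rose in 8 of 19 and fell in 4 (10 and 4 adjusted over the list alone, median 0.37, fry, adjusted p = 0.0234). Genes of neurons and photoreceptors fell in 8 of 21 with 1 higher (8 and 1 adjusted over the list alone, median -0.70, fry, adjusted p = 0.0266).

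Against day 30, effectors of the gut were higher in 13 of 36 cases (13 adjusted over the list alone, median 0.87, fry, adjusted p = 0.00734), with Def at 4.01 (SE 0.35). Ribosomal protein genes were higher in 80 of 81 (81 adjusted over the list alone, median 0.97, fry, adjusted p = 0.0032), and lipid genes lower in 11 of 33 with 1 higher (13 and 1 adjusted over the list alone, median -0.35, fry, adjusted p = 0.00734). FASN3 (-3.08) and FASN2 (-2.69), which are fat body markers, apolpp (-3.72) and the hemocyte gene Hml (-2.61) fell with them. The 30 fat body markers held 0.451% to 0.739% of male gut counts at day 30 and 0.0433% at day 45. In females they held 0.242% to 0.253%, then 0.0264% and 0.527% in the day 45 pair. Insulin and FOXO genes fell in 6 of 19 with 1 higher (6 and 1 adjusted over the list alone, median -0.46, fry, adjusted p = 0.0117). Enteroendocrine peptide genes rose in 8 of 12 (8 adjusted over the list alone, median 1.24, fry, adjusted p = 0.00313). Respiratory chain genes rose in 29 of 67 (46 adjusted over the list alone, median 0.51, fry, adjusted p = 0.0425), proteasome genes in 16 of 32 (20 adjusted over the list alone, median 0.43, fry, adjusted p = 0.00734) and glutathione and antioxidant genes in 15 of 47 (18 higher and 1 lower adjusted over the list alone, median 0.45, fry, adjusted p = 0.0414). Histone genes took 0.177% (SD 0.124) of female gut counts at day 30 and 0.00611% (SD 0.00650) at day 45, and 0.0674% (SD 0.0210) and 0.00352% in males. Sem1, a proteasome subunit gene, rose by 5.0 (SE 0.30) in gut and by 4.53 (SE 0.31) in fat body, and the mitochondrially encoded mt:ND6 by 4.0 (SE 0.40) and 4.60 (SE 0.33). The gut contrasts called 3568 of 11830 genes against day 5, 2240 higher and 1328 lower, and 2895 against day 30, 1490 higher and 1405 lower, by edgeR. For day 45 against day 5, scaling by the median of ratios moved the median of all genes from 0.05 to -0.17 and the share of higher calls from 62.8% to 41.8%. The change against day 30 ran along exonic length over all genes here too. Its median was 0.392 in the lowest quartile of length and -0.541 in the highest. Lists other than the ribosomal protein and histone genes were not corrected for it. As in fat body, the day 45 gut libraries differ from the earlier ones in depth, so age and any library batch cannot be told apart.

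**Figure D2:**
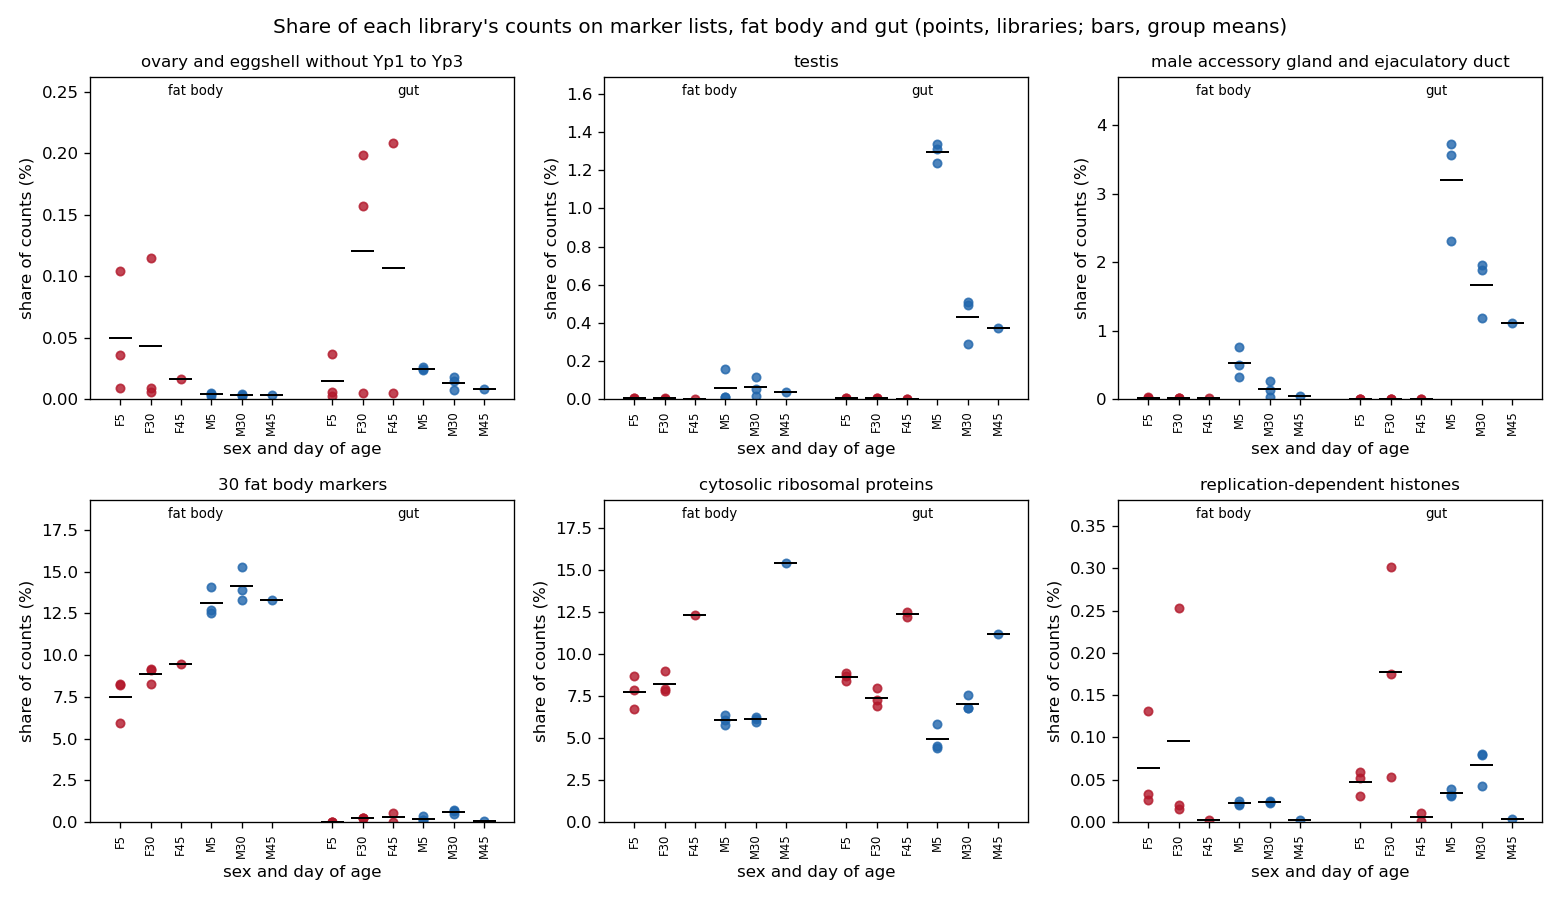
Share of each library's counts in percent (vertical axes) on 6 gene sets (panels) in fat body and gut, by sex and day of age, with libraries as points (red for females, blue for males) and group means as bars. Ribosomal protein genes held 12.3% and 15.4% of the counts in female and male fat body at day 45 against 8.23% and 6.10% at day 30, and histone genes in female gut went from 0.177% to 0.00611%.

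The sexes aged differently at day 30 in w1118 whole bodies, by a direct test of the male minus the female change. Of 49 digestive enzyme genes, 21 had the lower change in males and 1 the higher (22 and 1 adjusted over the list alone, median difference -1.04, fry, adjusted p = 0.0316). Jon25Bi went from 751 ± 228 to 51.0 ± 23.0 CPM in males and from 51.9 ± 4.35 to 257 ± 162 CPM in females (difference -6.19, SE 0.78). Respiratory chain genes had the lower change in males in 36 of 67 cases and the higher in 1 (47 and 1 adjusted over the list alone, median difference -0.70, fry, adjusted p = 0.017). Genes of neurons and photoreceptors differed the other way in 18 of 32 cases (23 adjusted over the list alone, median difference 0.74, fry, adjusted p = 0.00313). The synaptic gene Syt1 went from 58.2 ± 6.71 to 22.9 ± 3.64 CPM in females and from 129 ± 23.5 to 196 ± 8.06 CPM in males. Muscle genes did so in 10 of 27 cases with 1 opposite (15 and 2 adjusted over the list alone, median difference 0.47, fry, adjusted p = 0.00393), with Unc-89 at 2.39 (SE 0.32). Clock genes (3 of 10 with the higher change in males, 4 adjusted over the list alone, median difference 0.67, fry, adjusted p = 0.0102) and insulin and FOXO genes (7 of 22, or 8 higher and 2 lower adjusted over the list alone, median difference 0.41, fry, adjusted p = 0.0144) differed that way too. Proteasome genes (11 of 32 lower, 14 adjusted over the list alone, median difference -0.44, fry, adjusted p = 0.0425) and glutathione and antioxidant genes (9 of 50 lower, 9 adjusted over the list alone, median difference -0.48, fry, adjusted p = 0.0158) had the lower change in males. DptA differed by -5.63 (SE 0.95, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00106), and 7 of 40 effectors differed that way (2 adjusted over the list alone, median difference -2.05, fry, adjusted p = 0.0625). In all 2534 genes differed, 1981 with the higher change in males and 553 with the higher change in females. The count was 1070 without male day 5 replicate 1, 1477 without male day 30 replicate 1, 1640 without female day 5 replicate 2 and 1673 without female day 30 replicate 2.

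In OregonR whole bodies 107 genes had a sex difference, 21 with the higher change in males and 86 in females, and 1428 had an unadjusted p under 0.05. DESeq2 called 252 and limma with trend 226. Digestive enzymes again differed, in 13 of 49 cases (28 lower and 2 higher adjusted over the list alone, median difference -1.10, fry, adjusted p = 0.0117), among them the lipase gene Lip3 (-4.99, SE 0.63) and the amylase-related Amyrel (-4.79, SE 0.66). DptA differed by -4.75 (SE 1.04) and AttD by -6.05 (SE 1.10), and the heat shock gene Hsp22 by 2.44 (SE 0.38, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00644). Heat shock genes passed as a list with 1 of 25 called (1 adjusted over the list alone, median difference 0.36, fry, adjusted p = 0.0414). The count was 6 without female day 5 replicate 1, 19 without male day 30 replicate 1, 27 without female day 30 replicate 1, 37 without male day 5 replicate 2 and 49 without female day 5 replicate 2. In fat body 2 genes differed by edgeR, CG10469 (4.29, SE 0.45) and CG16775 (-8.54, SE 0.94), both at a Benjamini-Hochberg adjusted p of 0.00743. Limma with trend gave 36 and DESeq2 gave 81, and 668 genes had an unadjusted p under 0.05. Without female day 30 replicate 2 the edgeR count was 20, and without male day 5 replicate 1 it was 4.

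In gut, ribosomal protein genes had the higher change in males in 75 of 81 cases (81 adjusted over the list alone, median difference 1.19, fry, adjusted p = 0.00734), with RpL37A at 1.37 (SE 0.29). Enteroendocrine peptide genes did so in 5 of 12 (6 higher and 1 lower adjusted over the list alone, median difference 1.44, fry, adjusted p = 0.00734), with AstA at 2.27 (SE 0.41). Malpighian tubule markers did so in 7 of 15 (14 higher and 1 lower adjusted over the list alone, median difference 1.31, fry, adjusted p = 0.00734), with Oatp58Db at 1.64 (SE 0.44). Clock genes did so in 2 of 9 (2 adjusted over the list alone, median difference 0.56, fry, adjusted p = 0.00872). Ribosomal protein genes took 5.83%, 4.38% and 4.54% of male gut counts at day 5 and 6.79%, 7.53% and 6.75% at day 30. In females they took 8.66%, 8.36% and 8.85%, then 6.88%, 7.23% and 7.98%. The lowest male shares are those of day 5 replicates 2 and 3, which may be repeats of the same sample. Cell cycle genes had the higher change in females in 11 of 39 cases (20 lower and 1 higher adjusted over the list alone), though their list test missed the threshold (median difference -2.13, fry, adjusted p = 0.17). Their share of female counts at day 30 was 0.064% in replicate 1, as in replicate 1 of day 5, and 0.232% and 0.286% in replicates 2 and 3. The rise of the ovary list without yolk genes, given above, was likewise in replicates 2 and 3 alone. The mitotic kinesin gene pav went from 1.60 ± 0.702 to 17.7 ± 13.5 CPM in females and from 7.5 ± 1.16 to 4.96 ± 0.804 CPM in males. Testis transcripts fell in share in the male guts, as given above. EdgeR called 1157 genes with the quasi-likelihood test, 805 with the higher change in males and 352 in females. Scaling by the median of ratios moved the median of all genes from 0.09 to -0.25 and the share with the higher change in males from 69.6% to 26.2%. The count was 121 without female day 30 replicate 2, 143 without male day 5 replicate 3, 168 without male day 5 replicate 2, 260 without male day 30 replicate 2, 388 without female day 30 replicate 3, 534 without female day 5 replicate 2, 681 without female day 5 replicate 3, 682 without male day 30 replicate 1 and 1798 without female day 30 replicate 1.

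The strains differed in their day 30 change of blood cell and photoreceptor genes in whole bodies. Hemocyte markers had the higher change in OregonR in 7 of 18 cases (12 adjusted over the list alone, median difference 0.80, fry, adjusted p = 0.00519), among them PPO2 (1.63, SE 0.29) and eater (1.53, SE 0.27). PPO2 went from 50.3 ± 4.77 to 1.68 ± 0.140 CPM in w1118 females and from 20.9 ± 7.56 to 2.94 ± 0.929 CPM in OregonR females. The flight muscle genes TpnC4 (2.93, SE 0.60) and fln (2.55, SE 0.40) fell further in w1118 too. Genes of neurons and photoreceptors had the lower change in OregonR in 7 of 32 cases (12 adjusted over the list alone, median difference -0.35, fry, adjusted p = 0.0362), with trpl at -1.15 (SE 0.16). Antimicrobial effectors were higher in OregonR in 3 of 40 cases (3 adjusted over the list alone), which did not pass as a list (median difference 1.13, fry, adjusted p = 0.182), while the Imd genes PGRP-SD (1.76, SE 0.29) and pirk (1.59, SE 0.38) differed. The sterol transport gene Npc1b went from 39.4 ± 5.46 to 590 ± 318 CPM in OregonR females and from 25.8 ± 0.688 to 19.1 ± 4.38 CPM in w1118 females (difference 2.99, SE 0.41, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00155). In all 598 of 12381 genes differed, 212 with the higher change in OregonR and 386 with the lower, and scaling by the median of ratios moved the share of the former from 35.5% to 60.3%. Strain and depth go together here, since w1118 whole bodies were sequenced more deeply. The count dropped without any of 6 w1118 libraries, to 161 (female day 5 replicate 2), 211 (male day 30 replicate 1), 222 (female day 30 replicate 1), 229 (male day 5 replicate 1), 318 (female day 5 replicate 1) and 391 (male day 30 replicate 2). The same held for 6 OregonR libraries, with 172 (female day 30 replicate 1), 213 (female day 5 replicate 2), 269 (female day 5 replicate 1), 296 (male day 5 replicate 1), 304 (male day 30 replicate 2) and 333 (male day 30 replicate 1).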

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

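The tests of a library batch, of fat body carry-over and of ovary carry-over were chosen after the results were seen, and so were the thinned counts and the refit without sex-biased genes. The list tests of sex and strain differences were added later too. The other tests in this part were planned. Sex and strain differences are listed here because a direct test of the difference passed. The age changes of ribosomal protein and histone genes and of gut effectors are listed because other explanations were examined for them.

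The change from day 5 to day 30 differed between the sexes for 2534 genes in w1118 whole body, 107 in OregonR whole body, 2 in fat body and 1157 in gut, and between the strains for 598. In w1118 whole body the median difference, male minus female, was -0.702 for the respiratory chain, -0.442 for the proteasome, -0.483 for glutathione and antioxidant genes and -1.04 for digestive enzymes. It was 0.413 for insulin and FOXO signalling, 0.473 for muscle, 0.742 for neurons and photoreceptors and 0.669 for the clock. In OregonR it was 0.36 for heat shock genes and -1.1 for digestive enzymes. In gut it was 1.19 for ribosomal proteins, 1.44 for enteroendocrine peptides, 1.31 for Malpighian tubule markers and 0.563 for the clock. Between the strains, OregonR minus w1118, it was 0.802 for hemocyte markers and -0.351 for neurons and photoreceptors.

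Ribosomal protein genes rose and replication-dependent histone genes were lower at day 45 than at day 30 in fat body and gut, with 6 of 24 histone genes called lower in fat body, 14 of 25 in gut and 0 of 24 in whole body. Thinning all libraries to the smallest total left the ribosomal median at 1.11 in fat body (1.15 before) and 0.945 in gut (0.969 before), which argues against depth. Removing the trend on exonic length left 0.627 in gut and 0.542 in fat body, so length may account for part of the rise. In w1118 whole bodies, all sequenced deeply, the median log2 change from day 30 to day 45 was 0.0965 for ribosomal and 0.479 for histone genes. In day 5 whole bodies the deeply sequenced w1118 libraries were already lower in histone genes than the OregonR ones. The median was -2.89 in females and -2.38 in males. Their ribosomal protein genes were higher, by medians of 0.592 in females and 1.46 in males. Strain and depth class go together there. A library batch shared by the deep libraries and age therefore cannot be told apart, and age stays open, untested.

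Antimicrobial effectors rose in gut at day 30 while fat body markers rose there too (19 of 29 called, median 2.48). At day 30 the gut level of apolpp, a lipoprotein gene of fat body, was 0.103 of its fat body level in females and 0.114 in males. The median rise of the 36 tested effectors was 0.0853 and 0.125 of their fat body level. This was 0.83 and 1.1 times the value of apolpp but 3.18 and 3.04 times the median of the 30 markers (0.0268 and 0.0412). The values of apolpp and the markers are day 30 levels, with day 5 not taken off. Gut apolpp stood at 488 CPM in females and 460 CPM in males at day 5, and at 2187 and 1307 CPM at day 30. A comparison of rise with rise would therefore give a higher ratio to apolpp. The markers were chosen for low levels in gut and include genes of other tissue, so fat body carried along and a rise in gut itself cannot be told apart for most effectors. In each sex 6 of the 36 rose by more CPM than fat body held. The median rise of 1.77 in males alone argues against ovary. Age stays open as a biological explanation, untested.

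The sex difference in gut came with a falling testis share in males and, in 2 of 3 day 30 female libraries, a higher share of ovary genes other than yolk genes. Of the 1157 genes, 242 were at least 4 times higher in whole bodies of either sex, as were 4214 of the 11830 tested. Such genes were called in 5.74% of cases, against 9.78% of all tested genes. That rate carries little weight. A sex-biased gene can lie near 0 in guts of the other sex, which widens the SE of its difference. S-Lap3, of the testis list, fell from 840 to 289 CPM in male guts. It stood at 0.656 and 0 CPM in female guts and was not called (SE 1.94). A refit without the sex-biased genes called 778 (67.2% as many), 606 of them among the 1157. The share left therefore does not measure what carried-over reproductive organs contribute. The 606 genes called again argue against sex-biased transcripts of these organs as the whole cause, though such transcripts may explain part. Carried transcripts without a sex bias were not tested. Sex stays open as a biological explanation, untested.

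Ages were reassigned among the libraries within each sex. In fat body and gut 100 of the 200 possible splits were used. In fat body at day 30 none of the other splits drawn gave as many genes (1 of 100 with the real one; 699 against at most 37), and the same held in gut (1 of 100; 1514 against 175), for the gut sex difference (1 of 100; 1157 against 614 among those drawn), the gut effector median (1 of 100; 1.77 against 1.35), the strain difference (1 of 100 drawn from 648; 598 against 500) and the 9 genes changed alike (1 of 100; highest other 0). Chance was excluded for the age results among these only if the libraries are separate samples, which the labels do not state. These results are the genes by age in fat body and gut and the gut effector median. Male day 5 gut replicates 2 and 3 may be repeats of the same sample. An effect of vial or dissection shared by a group is not excluded. On the same terms chance was excluded for day 45 against day 5 in gut (1 of 40, 3568 against 357). The same held for day 45 against day 30 in gut (1 of 40, 2895 against 16) and whole body (1 of 60, 1113 against 576). In gut the day 45 libraries were also the deep ones, so these splits cannot tell age from depth or a library batch. The splits break any age change too, so they cannot exclude chance for the sex and strain differences. For the 9 genes changed alike they say little, since the other splits gave at most 37 genes in fat body. For the 2 genes with a sex difference in fat body (4 of 100) the splits cannot exclude chance either. Another 3 splits gave as many and the highest gave 37, several times the real count, so the count of 2 carries little weight. The swap of ages in a single sex, which was not drawn, would give the 699 genes by age, so the splits point to the age structure of the samples. Chance was not excluded for the fat body effector median (62 of 100, 0.16 against -0.70). For day 45 against day 5 in whole body, 2 of 60 splits gave as many genes, with 3623 in another split against 2821.

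The 18 splits of each strain's whole bodies at day 30 were too few for a share under 0.05. For w1118 the real values and the highest others were 1723 and 2534 genes by age (2 splits as large), 2534 and 1723 by sex difference (1), and -0.04 and 1.03 for the effector median (16). For OregonR they were 826 and 238 (1), 107 and 826 (3), and 0.78 and 1.08 (3). Swapping the ages in a single sex turns the age contrast into the sex difference, so the split with 826 genes points to the age structure of the samples, as does the split with more genes than the real one in w1118. Among the 200 splits of gut that swap would give 1514 genes for the sex difference, more than the real 1157, and it was not among those drawn.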

How the results depend on the processing

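DESeq2, limma on log2(CPM + 1), each sex alone and the fits without day 45 were added after the data were seen, and the other settings were planned. The gut effector median, which passed its test, kept its sign in each setting. The effector medians of w1118 (-0.04) and fat body (0.16), which did not pass, changed sign in a single sex. Scaling by the median of ratios turned the balance of gut sex differences from 69.6% to 26.2% with the higher change in males. The cause of the moves was not tested. With a pseudocount of 0.1, gut at day 30 gave 2918 genes (1514 in the report), the OregonR sex difference 278, the gut sex difference 2883, the genes changed alike 15, and the OregonR effector median 0.80 (fry, adjusted p = 0.0336). With limma on log2(CPM + 1) there were 3723 genes in gut at day 30, sex differences of 226 in OregonR, 36 in fat body and 3641 in gut, 1167 for strain and 20 changed alike. DESeq2 gave 1170 in fat body at day 30, sex differences of 252 in OregonR and 81 in fat body, and 32 changed alike, and it has no fry value for the medians. Scaling by the median of ratios gave 720 for the gut sex difference and 385 for strain. Females alone gave 746 in w1118 whole body, 291 in fat body and an effector median of 0.87 in w1118, and males alone 3947 in w1118 whole body, 289 in OregonR, 67 in fat body, 3429 in gut and an effector median of -0.29 in fat body. Without day 45, 15 genes changed alike and the OregonR effector median was 0.77 (fry, adjusted p = 0.0498). Replicate numbers did not pair the samples: of 20 same-number pairs 3 correlated above 0.1 and 12 correlated best with their own number, and with the number as a block the OregonR effector median was 0.78 (fry, adjusted p = 0.0486). Counts of day 45 stayed within 1.5 times under the settings that keep all libraries.

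Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave ranges of 728 to 1739 genes at day 30 in w1118 whole body, 448 to 857 in OregonR, 322 to 863 in fat body and 818 to 1640 in gut, and 481 to 1209 for day 45 against day 30 in whole body. Sex differences ranged from 1070 to 2509 in w1118, 6 to 141 in OregonR, 2 to 20 in fat body and 121 to 1798 in gut, strain from 161 to 768 and the genes changed alike from 3 to 14. Effector medians ranged from -0.23 to 0.23 in w1118, where the sign turned without female day 5 replicate 1 (0.04), female day 30 replicate 1 (0.01), male day 5 replicate 1 (0.23) and male day 30 replicate 1 (0.004), and from 0.63 to 1.24 in OregonR.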

Other observations

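Calls that held in each fit with a library left out numbered 591 of 1723 in w1118 whole body, 367 of 826 in OregonR, 267 of 699 in fat body and 674 of 1514 in gut at day 30. For day 45 against day 5 they were 1300 of 2821 in whole body, 2818 of 3441 in fat body and 2434 of 3568 in gut. For these tissues 6 fat body and 8 gut libraries could be left out. The lone day 45 libraries, which carry the contrast, could not, so the fat body and gut counts say little about them. For sex differences they were 719 of 2534, 6 of 107, 2 of 2 and 110 of 1157, and for strain 107 of 598.

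Muscle transcripts in dissected fat body and cuticle transcripts in young fat body vary between libraries, so the amount of attached tissue stays open as a source of these differences.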
